A study of Lithobates sylvaticus with 51 samples.

How the data were processed

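Messenger RNA of the spleen and of ventral skin was sequenced from wild-caught adult wood frogs kept in outdoor enclosures through a winter and sampled at 4 times, per the series' design text. Per the labels' protocols, tissues were kept in RNAlater and frozen, total RNA was extracted with TRI reagent and a purification column, and libraries were made with an Illumina stranded mRNA kit. The authors deposited whole-number read counts per identifier for each library, with no normalization, per the file contents. Per the submitters' processing notes, Trimmomatic 0.39, HISAT2 and StringTie were used; the order of use, the genome build, the counting program and its strand setting are not given in the sources used here. The identifiers carry MSTRG numbers, which number assembled loci, and no file pairs them with gene symbols. Reads of near-identical copies, overlapping loci and antisense loci can be divided or merged by counting, so each identifier may hold part of a gene or more than 1 gene, and its count is uncertain to that extent.

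Each deposited file held 50209 identifiers and 5 tally lines for reads that were not assigned, which were left out of library sizes and tests. Genes took 23.6 to 71.0% of all reads tallied. Reads with several alignments took 53.8% in Emergence spleen replicate 1 and 6.6 to 12.6% in the other used libraries. Groups and replicate numbers were taken from the sample labels. Libraries with under 1000000 gene counts were left out: 10 of 51, each with 5 counts or fewer. They were Fall spleen replicates 8 and 9, Fall ventral skin replicate 8, Winter spleen replicate 4, Winter ventral skin replicates 1, 2 and 8, Emergence spleen replicate 6, Emergence ventral skin replicate 1 and Spring ventral skin replicate 2. In the 85 pairs of used libraries within a group, chi-square per degree of freedom over identifiers with a summed count of at least 10 was 14.4 to 457, so no pair was within sampling noise. Within a tissue, each library was treated as a separate frog of its time, since the spleen is taken whole and a frog can be sampled once.

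Counts were tested with edgeR 4.0.16 (R 4.3.3): TMM scaling, filterByExpr with its default minimum count of 10 and total of 15, and quasi-likelihood fits with robust estimation. For each tissue, 1 fit held all 4 times, with the contrasts Winter against Fall, Emergence against Winter, Spring against Emergence and Spring against Fall and a joint test across the times. A fit of both tissues tested whether the change between times differed between tissues. Adjusted p-values are Benjamini-Hochberg values within each contrast, and an identifier was called at an adjusted p under 0.05. The standard error of a log2 change is its size divided by the square root of the F statistic. These groups, tests, the rule for named identifiers and the alternatives were fixed before the data were examined. The rule took up to 2 rising and 2 falling identifiers per contrast, those with the largest log2 change among called identifiers with an average log2 CPM of at least 1 and no overlap between the libraries of both groups, and for the difference between tissues the 2 with the smallest p for each sign. This is the rule set for files without gene names. The 27 gene lists fixed beforehand (1177 symbols) matched 0 identifiers, so 0 lists were tested.

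CPM are counts per 1000000 gene counts. Where a group had no counts of an identifier, the fold is a lower bound from a floor of 3 counts over the group. Where it had 1 to 3 counts, the ratio of pooled counts is given with an exact 95% Poisson interval. Shares of 1 library have 95% Wilson intervals. These cover counting error only. The depth limits the precision most in Winter spleen, where a floor of 3 counts over the group equals 0.144 CPM, against 0.0215 in Fall spleen.

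The fits were tested on simulated counts drawn from the mean of each identifier and the size of each library, with 100 identifiers changed 2-fold and 100 changed 4-fold. For Winter against Fall, 2% of the 2-fold and 43% of the 4-fold changes were recovered in spleen (20597 identifiers, 1 false call of 46), and 19% and 62% in ventral skin (22056 identifiers, 4 false calls of 85). For Emergence against Winter they were 5% and 51% in spleen (1 false call of 57) and 17% and 53% in ventral skin (0 of 70).

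Spleen and skin libraries with the same time and number were taken as 1 frog; 18 frogs had both. This pairing was checked with identifiers above a mean log2(CPM + 1) of 1.5 and an SD of 0.5 in both tissues, of which the 150 with the highest correlation between tissues in the other frogs were used for each spleen library; 17 of 18 pairs were recovered. The fit of both tissues took the libraries of 1 frog as independent, and the frog was a block in an alternative fit. Numbers were not taken to pair libraries across times, where the animals differ. Positions between Fall and Winter were computed on log2 CPM (prior count 2) over identifiers with an average log2 CPM of at least 1 that were called in Winter against Fall without the library labelled Emergence spleen replicate 8, and compared between Emergence and Spring with an exact two-sided permutation test of the means. The group of 59 identifiers was built from identifiers with a mean of at least 5 CPM in spleen whose log2 CPM correlated at 0.85 or more with MSTRG.43154 over the spleen libraries. For the comparisons that share Fall libraries, unchanged counts were simulated and the Fall libraries were divided between the comparisons in 10 ways.

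Alternatives were DESeq2 size factors in the edgeR fit, DESeq2 1.42.0, limma 3.58.1 voom with sample quality weights, no filter on low counts, library minimums of 5 M (M, 1000000) and of 10000 counts, a covariate for the form of the library name, a fit of only the 2 groups compared, the replicate number or the frog as a block, and each library left out in turn. Sequencing dates are not given in the sources used here; library numbers largely ran with the time of sampling. The frog check, the positions, the group of 59 identifiers, the sets enriched in 1 tissue, thinning of every library to the smallest total of its tissue, the fits without the library labelled Emergence spleen replicate 8 in all contrasts or without the 4 libraries rich in the 59 identifiers, and the contrasts Emergence against Fall and Spring against Winter were chosen after seeing the data. Splits of the libraries into groups of the same sizes were drawn at random, 100 per result with the real one; for differences between tissues the frogs with both tissues were split and all 41 libraries refitted in the fit without a block, and for Spring against Emergence all 35 such splits were run.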

Results

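The wood frog, Lithobates sylvaticus, is a North American frog that overwinters under leaf litter and tolerates freezing. Messenger RNA was sequenced from the spleen, an immune organ, and from a piece of ventral skin of adult frogs held in outdoor enclosures, at 4 times called Fall, Winter, Emergence and Spring. Of 51 deposited libraries, 41 held enough counts to be used: 20 of spleen, 5 per time, and 21 of ventral skin, 6 in Fall and 5 at each other time. The other 10 held 5 or fewer counts each. The used libraries held 1.08 to 47.2 M counts (M, 1000000) assigned to 50209 identifiers, and spleen depth was uneven: Fall spleen libraries held 11.2 to 47.2 M counts, and Winter spleen libraries held 1.08 to 12.2 M with 4 of the 5 under 3 M. Emergence spleen libraries held 3.2 to 29.8 M and Spring spleen libraries 3.21 to 30 M. Ventral skin libraries held 18.9 to 32.8 M in Fall, 14.7 to 29.7 M in Winter, 11.3 to 38.4 M in Emergence and 10.8 to 45.3 M in Spring. The identifiers number assembled loci (MSTRG) and the files do not pair them with gene names, so they are given as deposited, and gene lists fixed beforehand for immunity, metabolism and cell types matched 0 of them. Identifiers are named here by the rule in the processing account, with counts per 1000000 (CPM) as mean ± SD over libraries.

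Spleen and skin libraries of 1 frog could be recognised by their expression. Over 150 identifiers whose level between frogs ran in parallel in both tissues, 17 of the 18 spleen libraries with a skin library of the same label correlated best with that library, with Pearson r of 0.83 to 0.94 against -0.33 to 0.42 for unmatched pairs of these and of 2 spleen libraries with no skin partner. These correlations are across identifiers, which are not independent replicates. The exception was the library labelled Emergence spleen replicate 8. Its r with the skin library of its own label was 0.07, and its r with Fall ventral skin replicate 9 was 0.90, the next highest being 0.18. Counts that involve Emergence spleen are therefore given with and without the library labelled Emergence spleen replicate 8.

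**Figure D1:**
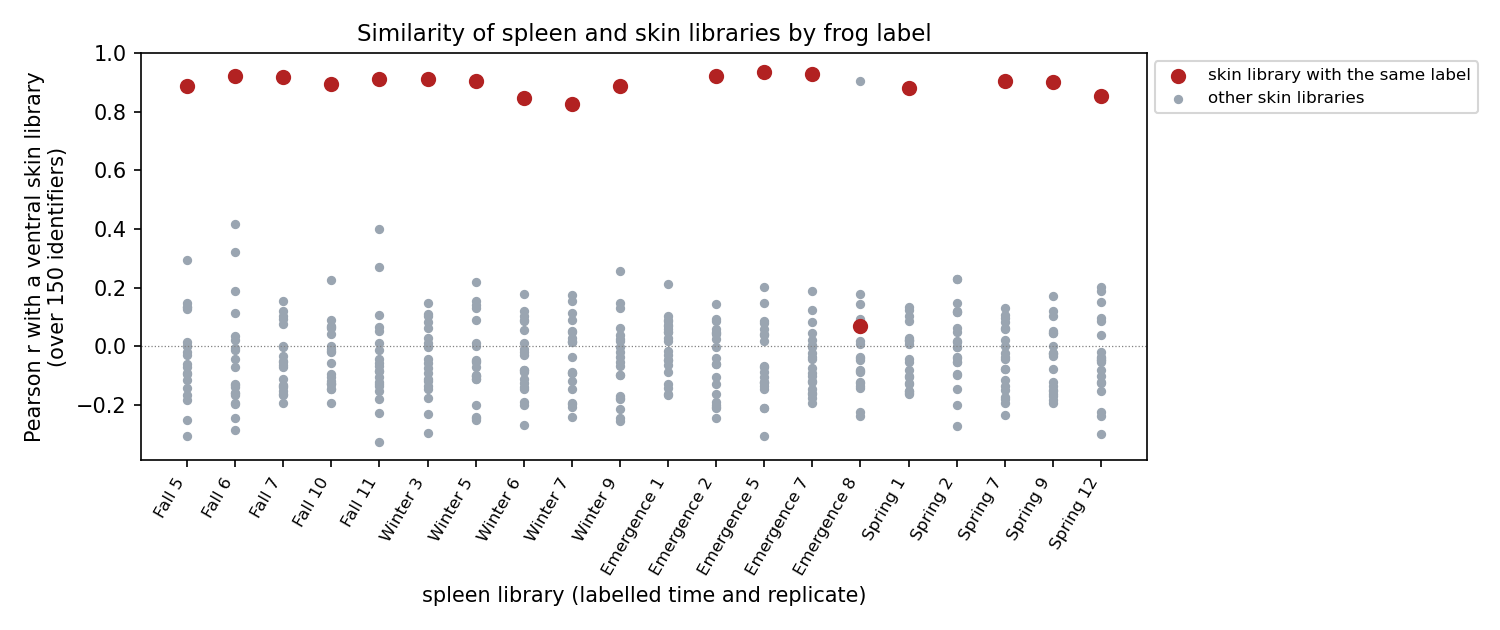
Pearson correlation (vertical axis, no unit) of each spleen library (horizontal axis, labelled time and replicate) with each of the 21 ventral skin libraries over 150 frog-specific identifiers. Large red points mark the skin library of the same label and small grey points the others; red points lie at 0.83 to 0.94 except for the library labelled Emergence spleen replicate 8, at 0.07, whose highest point is Fall ventral skin replicate 9 at 0.90.

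A group of 59 identifiers made up a large part of 4 spleen libraries and little of the rest. Its share of counts was 27.4% in Winter spleen replicate 7 (95% Wilson interval 27.3 to 27.5), 27.2% in Emergence replicate 7, 19.5% in Spring replicate 1 and 13.7% in Spring replicate 9. It was at most 1.69% in the other 16 spleen libraries and at most 0.039% in skin. MSTRG.43154, the abundant identifier from which the group was built, reached 64200 CPM in Winter spleen replicate 7 and had 0 counts in Spring spleen replicates 2 and 12. The 4 libraries belonged to 3 times, none of them Fall. Intervals here and floors cited for identifiers with no counts cover counting error only.

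The first comparison asked what had changed in ventral skin by Winter. MSTRG.15881 showed the largest rise among the named identifiers, from 0.152 ± 0.153 CPM in Fall (n = 6) to 3160 ± 1480 in Winter (n = 5), a log2 change of 14.11 (SE 1.12, adjusted p 6.86e-08, edgeR). The log2 change was 14.82 without Fall skin replicate 7. MSTRG.49735 rose from 0.0124 ± 0.0194 CPM in Fall to between 0.546 and 560 CPM in each Winter library (adjusted p 0.000366, edgeR). With 2 counts in all Fall libraries, the pooled ratio was 19200 with a counting interval of 5310 to 158000. It was 10500 without Winter skin replicate 6, 31000 without Fall skin 6 and 32400 without Fall skin 10. In the other direction, MSTRG.40325 fell from 295 ± 174 CPM to 0.0172 ± 0.0243, with 2 counts left in Winter, a pooled ratio of 17400 (4830 to 144000; adjusted p 2.44e-09, edgeR). It was 28800 without Winter skin replicate 3. MSTRG.37764 fell from 54.8 ± 51.5 to 0.0204 ± 0.0305 CPM, also with 2 counts left, a ratio of 2910 (806 to 24100; adjusted p 1.19e-07, edgeR). The ratio was 5060 without Winter skin replicate 5. Across the skin, 8967 of 22806 tested identifiers changed, 4542 higher and 4425 lower in Winter, and 6244 of them by over 2-fold. Of the 874 changed by over 16-fold, 576 were higher and 298 lower. The count stayed between 7882 and 8628 when any 1 of the 11 libraries was left out. The near balance of directions turned with limma voom (4470 higher, 4609 lower) and in a fit of only the 2 groups (4170 and 4348). The call of MSTRG.49735 was lost with limma voom (adjusted p 0.277), where its 5 Winter libraries ranged from 8 to 16367 counts.

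**Figure D2:**
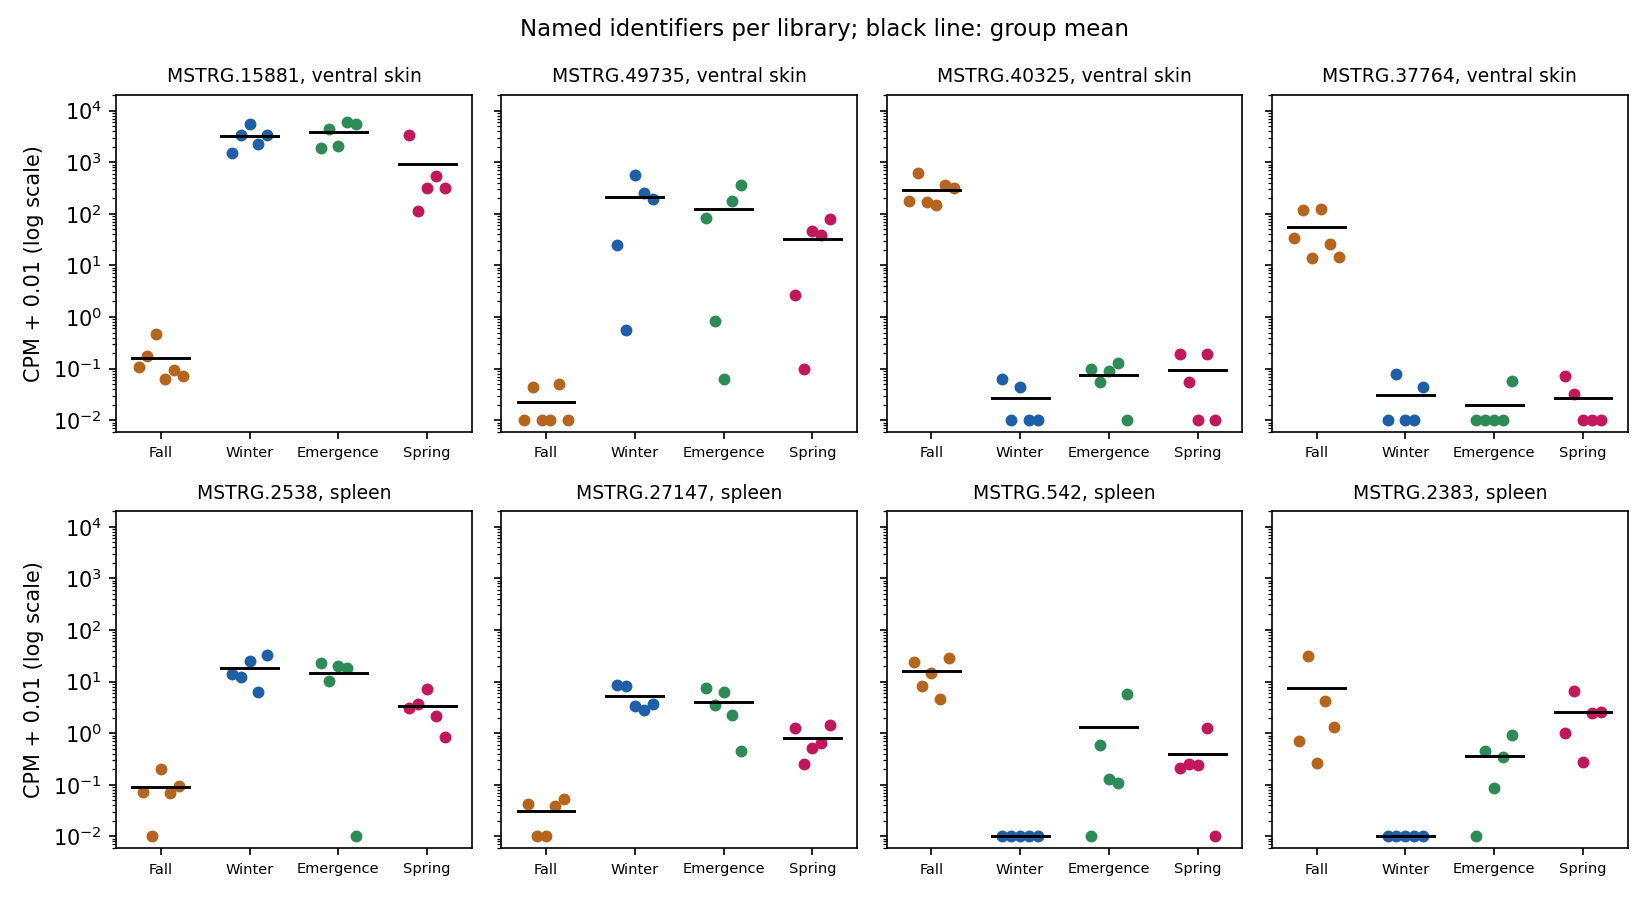
CPM plus 0.01 (log scale) of the identifiers named for Winter against Fall, in ventral skin (upper panels) and spleen (lower panels), by time of sampling; points are libraries and black lines group means. MSTRG.15881 lies at a mean of 0.152 CPM in Fall skin and 3160 in Winter skin, and MSTRG.542 at 16.1 in Fall spleen and 0 in Winter spleen; the Emergence spleen points include the library labelled replicate 8.

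In the spleen, MSTRG.2538 rose from 0.0793 ± 0.0691 CPM in Fall to 18.2 ± 10.9 in Winter (n = 5 each), a log2 change of 7.71 (SE 1.01, adjusted p 0.00026, edgeR). MSTRG.27147 rose from 0.0207 ± 0.0195 to 5.37 ± 2.86 CPM, a log2 change of 7.33 (SE 0.83, adjusted p 9.9e-05, edgeR). MSTRG.542, at 16.1 ± 10.4 CPM in Fall, had no counts in Winter, at least 129-fold lower at a floor of 3 counts over the Winter group (adjusted p 0.00422, edgeR). Without Winter spleen replicate 3, the deepest of its group, the bound was 53.5-fold. MSTRG.2383, at 7.5 ± 13.3 CPM in Fall, also had no counts in Winter, at least 28.7-fold lower at the same floor (adjusted p 0.00988, edgeR). That bound was 12.4-fold without Fall spleen replicate 6 and 11.9-fold without Winter spleen replicate 3, and its call was lost with limma voom (adjusted p 0.111) and with only libraries of at least 5 M counts (adjusted p 0.249). Of 21239 tested identifiers, 4888 changed, 1982 higher and 2906 lower in Winter, and 4014 of them by over 2-fold. The count was 3354 to 5443 with 1 library left out. It was 2635 of 10828 tested with every spleen library thinned to the smallest total, since fewer identifiers then passed the count filter. A minimum of 5 M counts per library leaves 1 Winter spleen library. There the count was far lower and the balance of directions turned.

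Many identifiers changed in the same direction in both tissues between Fall and Winter. Among 18548 tested in both, 1242 were higher in both, where 353 would be shared by independent lists of 1824 in spleen and 3588 in skin, and 20 went up in spleen and down in skin, where independence gives 379. For falls the shared number was 1573 against 531, and 24 fell in spleen and rose in skin against 494. Most of these frogs gave both tissues, so the lists are not independent.

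The change also differed between tissues for part of the identifiers. MSTRG.21991 fell in spleen from 304 ± 18.9 to 156 ± 27.2 CPM and rose in skin from 173 ± 49.8 to 1250 ± 273, a skin minus spleen difference in log2 change of 3.77 (SE 0.34, adjusted p 9.52e-09, edgeR). MSTRG.14461 rose in skin from 0.325 ± 0.366 to 90.5 ± 41.9 CPM, with 7.1 ± 4.82 and 3.2 ± 4.05 in spleen, a difference of 8.98 (SE 1.06, adjusted p 3.45e-06, edgeR). The difference was 10.32 without Winter spleen replicate 3 and 9.75 without Fall skin replicate 9. MSTRG.40325, the skin identifier that fell, was at 0.0709 ± 0.0758 CPM in Fall spleen and 0.268 ± 0.41 in Winter spleen (adjusted p of the difference 1.68e-06, edgeR). These spleen levels rest on 12 counts in Fall and 6 in Winter, too few for the count filter of the spleen fit. Without Winter spleen replicate 3 the adjusted p of the difference was 0.0456 (edgeR). MSTRG.40327 went from 11.6 ± 5.66 to 1.34 ± 0.676 CPM in skin (adjusted p of the difference 6.92e-05, edgeR). It had 2 counts in Fall spleen and 14 in Winter spleen, also too few for the spleen fit. This call rested on Winter spleen replicate 3, without which the adjusted p was 1, and was also lost after thinning (adjusted p 0.0905, edgeR). In all, 709 of 27591 identifiers differed, 472 with the more positive change in skin and 237 with the more negative one.

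With the frog as a block over 18 frogs, 263 identifiers differed between tissues, 186 and 77 by sign, of which 211 were among the 709. Without the library labelled Emergence spleen replicate 8 the blocked count was 408. The balance of signs did not hold: with DESeq2 size factors in the same edgeR fit, 489 differed, 199 with the more positive change in skin and 290 with the more negative, and the median over all identifiers moved from 0.18 to -0.05. Without the library labelled Emergence spleen replicate 8, 580 differed, 260 more positive and 320 more negative in skin. With the scaling unchanged, more negative changes in skin also outnumbered more positive ones in 7 of 21 fits that left out 1 Fall or Winter library: 264 more positive and 484 more negative without Fall spleen 6, 265 and 357 without Fall spleen 11, 241 and 374 without Winter spleen 5, 327 and 373 without Winter spleen 9, and likewise without Fall spleen 7, Winter spleen 6 or Winter skin 7. DESeq2 itself called 1678, 564 more positive and 1114 more negative, and limma voom 1669, 809 and 860. The 709 became 274 without Fall spleen replicate 5, 257 without Fall spleen 10, 424 without Fall spleen 7, 418 without Fall skin 9, 444 without Winter spleen 3, 280 without Winter spleen 6, 320 without Winter spleen 7, 307 without Winter skin 7, 317 without Winter skin 9, 289 without Winter skin 6 and 395 without Winter skin 5. It became 97 with a minimum of 5 M counts per library (19 more positive, 78 more negative), 170 after thinning (68 and 102) and 323 with no filter on low counts.

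Emergence against Winter asked what differed when frogs came out of overwintering. In skin, edgeR called 0 of 22806 identifiers, with 2157 at an unadjusted p under 0.05; DESeq2 called 137 and limma voom 1. MSTRG.15881 stood at 3920 CPM in Emergence, beside 3160 in Winter. In spleen, edgeR called 0 of 21239, with 2648 at an unadjusted p under 0.05; DESeq2 called 252 and limma voom 0. Leaving out 1 library gave 3 calls in spleen without Winter replicate 3 and 13 without Winter replicate 9, and in skin 2 without Emergence replicate 5 and 1 without Winter replicate 6. Without the library labelled Emergence spleen replicate 8 the spleen count was again 0, with 2402 at an unadjusted p under 0.05. The difference between tissues was called for 0 of 27591 identifiers (1903 at an unadjusted p under 0.05), by DESeq2 for 114, with the frog as a block for 1, without Winter skin replicate 5 for 1, and without the library labelled Emergence spleen replicate 8 for 0 (2 with the frog as a block). A count of 0 here does not show equal expression. In data simulated for Emergence against Winter at the depths of these libraries, edgeR found 5% of 2-fold and 51% of 4-fold changes in spleen, and 17% and 53% in skin. These rates hold for 100 identifiers changed by each fold and could differ for a broader change. The spleen spread came from a fit that kept the library labelled Emergence spleen replicate 8.

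**Figure D3:**
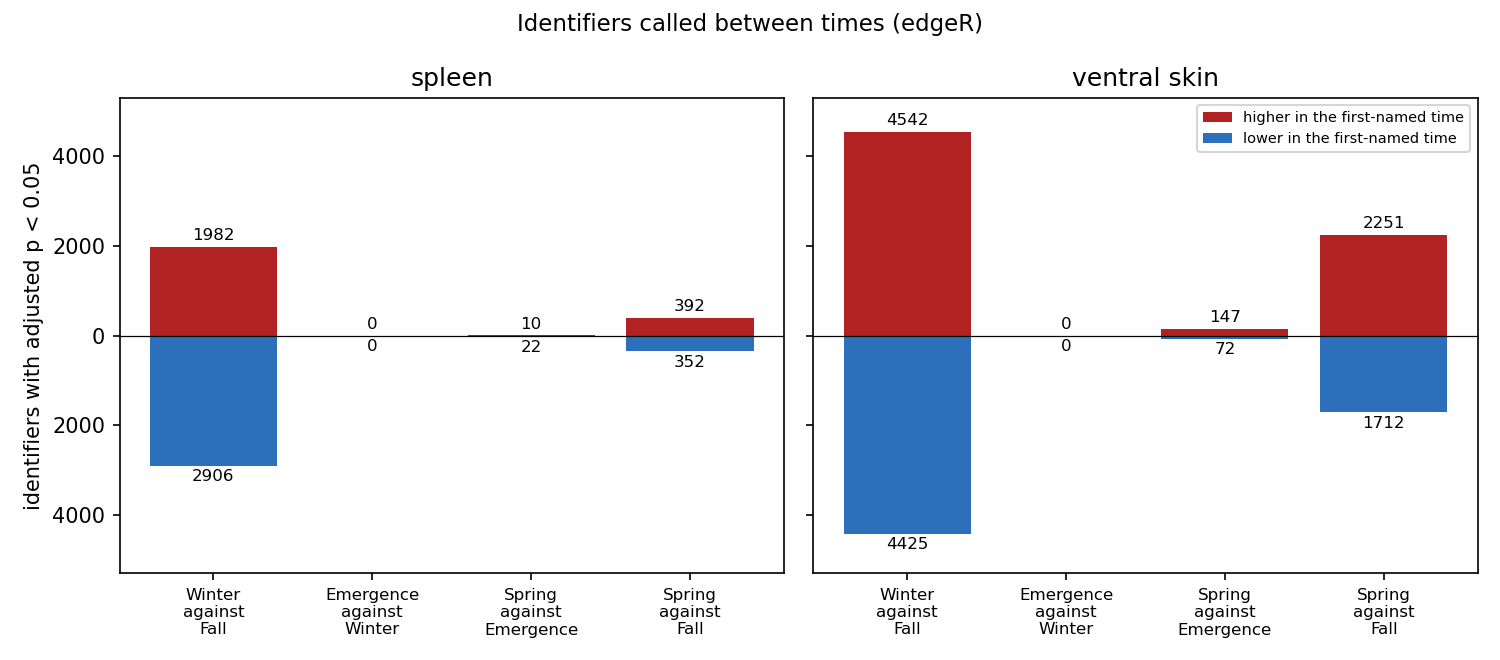
Number of identifiers with an adjusted p under 0.05 (edgeR) in each comparison, for spleen and ventral skin; red bars above 0 are higher and blue bars below 0 lower in the first-named time. Winter against Fall gave 4888 in spleen and 8967 in skin, and Emergence against Winter gave 0 in both.

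Between Emergence and Spring, MSTRG.43787 rose in skin from 0.0829 ± 0.0827 to 1.97 ± 1.1 CPM, a log2 change of 4.28 (SE 0.98, adjusted p 0.0411, edgeR), and MSTRG.40601 rose from 1.25 ± 1.26 to 26.2 ± 17, a log2 change of 4.22 (SE 0.81, adjusted p 0.0221, edgeR). Both were at higher levels in Fall, 4.86 and 43.3 CPM, than in Emergence. MSTRG.46208 fell from 13.1 ± 4.91 to 0.0507 ± 0.0387 CPM, a log2 change of -8.07 (SE 1.64, adjusted p 0.0283, edgeR), and MSTRG.6696 fell from 3.41 ± 5.41 to 0.0287 ± 0.0306, a log2 change of -6.70 (SE 1.32, adjusted p 0.0253, edgeR). In all, 219 of 22806 identifiers changed in skin, 147 higher and 72 lower in Spring. Of these, 89% had been called in Winter against Fall with the opposite sign and 5 of the 219 with the same sign. The calls were sensitive to single libraries. With 10 libraries left out in turn, the call of MSTRG.43787 was lost in 7 cases (highest adjusted p 0.0985, edgeR), that of MSTRG.40601 in 2 (0.066), that of MSTRG.46208 in 5 (0.0889) and that of MSTRG.6696 in 4 (0.0855). With 1 library left out, the log2 change of MSTRG.6696 was -4.94 without Emergence replicate 8, that of MSTRG.43787 was 4.91 without Emergence 6 and that of MSTRG.40601 was 5.00 without Emergence 7. The call of MSTRG.43787 was also lost with limma voom (adjusted p 0.271), with no filter on low counts (0.0731) and with a covariate for the form of the library name (0.0594). MSTRG.40601 was lost in a fit of only the 2 groups (0.111), MSTRG.46208 with no filter (0.0646) and MSTRG.6696 with limma voom (0.211).

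The skin count of 219 became 65 without Emergence replicate 5, 30 without Emergence 7, 132 without Emergence 8, 338 without Emergence 6, 558 without Spring 1, 23 without Spring 7, 108 without Spring 8, 38 without Spring 9 and 45 without Spring 12. DESeq2 called 1074 and limma voom 141, a fit of only the 2 groups gave 11, and no filter on low counts gave 69.

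In the spleen, MSTRG.29640 rose from 1.27 ± 0.328 CPM in Emergence to 9.3 ± 5.53 in Spring, a log2 change of 2.72 (SE 0.52, adjusted p 0.0384, edgeR), and MSTRG.46569 from 2.27 ± 0.693 to 11.8 ± 5.41, a log2 change of 2.20 (SE 0.38, adjusted p 0.0347, edgeR). MSTRG.28888 fell from 8.79 ± 11 to 1.05 ± 0.569 CPM, a log2 change of -3.29 (SE 0.65, adjusted p 0.0445, edgeR) that was -2.21 without Emergence replicate 5, and MSTRG.21596 from 6.14 ± 3.16 to 0.928 ± 0.217, a log2 change of -2.86 (SE 0.47, adjusted p 0.0234, edgeR). Only 32 of 21239 identifiers changed, 10 higher and 22 lower, with 3325 at an unadjusted p under 0.05. Of the 32, 9 had been called in Winter against Fall with the opposite sign, 6 with the same sign and 17 not at all. These 4 named calls were each lost when certain single libraries were left out, in 7, 6, 8 and 5 of 10 cases for MSTRG.29640, MSTRG.46569, MSTRG.28888 and MSTRG.21596, with highest adjusted p of 0.145, 0.138, 0.162 and 0.134 (edgeR). All 4 were also lost, in the same order, with no filter on low counts (adjusted p 0.0799, 0.0694, 0.0769 and 0.0516), with the naming covariate (0.0658, 0.065, 0.0854 and 0.0519) and in a fit of only the 2 groups (0.153, 0.153, 0.178 and 0.132). MSTRG.28888 was further lost without the 4 libraries rich in the 59 identifiers (0.0654). None of the 4 calls was lost without the library labelled Emergence spleen replicate 8. The Emergence means and the choice of the 4 include that library, so other identifiers could lead without it.

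Without the library labelled Emergence spleen replicate 8, 687 spleen identifiers changed, 306 higher and 381 lower in Spring, of which 373 had been called in Winter against Fall with the opposite sign and 22 with the same sign. The count of 32 became 0 without Emergence 5, Spring 2 or Spring 7, 1 without Spring 12, 7 without Emergence 2, 11 without Emergence 1 or Emergence 7, 52 without Spring 1 and 108, with 65 higher and 43 lower, without Spring 9. It became 344, with 250 higher and 94 lower in Spring, without the 4 libraries rich in the 59 identifiers, and 348 with the 5 M minimum, 14 after thinning, 4 with the naming covariate and 0 with no filter or in a fit of only the 2 groups. DESeq2 called 1090, 560 higher and 530 lower, and limma voom 1403, 788 higher and 615 lower. The change did not differ between tissues for any of 27591 identifiers in edgeR (2387 at an unadjusted p under 0.05), while DESeq2 called 265 and limma voom 8. Leaving out 1 library gave 20 without Emergence spleen 2, 7 without Emergence spleen 5, 33 without Emergence spleen 7, 13 without the library labelled Emergence spleen replicate 8, 3 without Spring skin 1 and 27 without Spring spleen 9.

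The last comparison asked how far Spring frogs still differed from those of the preceding Fall. In skin, MSTRG.15881 was higher in Spring, at 939 ± 1390 CPM against 0.152 ± 0.153 (log2 change 12.25, SE 1.06, adjusted p 4.32e-07, edgeR; 10.60 without Spring skin replicate 1 and 12.96 without Fall skin 7), as was MSTRG.49735 at 33 ± 32.4 CPM, a pooled ratio of 2510 (694 to 20700; adjusted p 0.00509, edgeR) that ranged from 1310 without Spring skin replicate 12 to 4240 without Fall skin 10, although limma voom did not call the latter (adjusted p 0.501). MSTRG.40325 stayed low at 0.0826 ± 0.0946 CPM (log2 change -12.51, SE 0.74, adjusted p 6.72e-09, edgeR; -13.13 without Spring skin 1). MSTRG.4062 had no counts in Spring against 26.3 ± 44.4 CPM in Fall, at least 932-fold lower (adjusted p 0.00359, edgeR; limma voom 0.177), or 366-fold without Fall skin replicate 9 and 610-fold without Spring skin replicate 7. Of 22806 identifiers, 3963 differed, 2251 higher and 1712 lower in Spring, and the count was 3093 to 3407 with 1 library left out. A fit of only the 2 groups gave 2046 higher and 2054 lower.

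In the spleen, MSTRG.41790 had no counts in Fall and 6.3 ± 6.86 CPM in Spring, at least 259-fold higher (adjusted p 0.0104, edgeR), or 126-fold without Spring spleen replicate 1, 172-fold without Fall spleen 11 and 389-fold without Spring spleen 7. MSTRG.38126 rose from 0.0652 ± 0.0821 to 3.79 ± 2.16 CPM, a log2 change of 5.98 (SE 0.98, adjusted p 0.00515, edgeR). The log2 change was 6.57 without Fall replicate 5 and 5.25 without the 4 libraries rich in the 59 identifiers, and the call was lost after thinning (adjusted p 0.06). MSTRG.541 was lower, at 2.38 ± 3.06 CPM against 256 ± 80.4 (log2 change -6.61, SE 1.30, adjusted p 0.0109, edgeR; -8.21 without Spring replicate 1). MSTRG.37442 went from 4.34 ± 3.7 to 0.0133 ± 0.0298 CPM with 2 counts left, a pooled ratio of 210 (57.9 to 1740; adjusted p 0.0488, edgeR). Without Spring spleen replicate 7, which holds both counts, it was at least 85.1-fold lower, and its call was lost in 10 of 12 cases with 1 library left out (highest adjusted p 0.124). That call was also lost with no filter (adjusted p 0.0889), limma voom (0.125), the 5 M minimum (0.0909), the naming covariate (0.0562) and without the 4 libraries rich in the 59 identifiers (0.102). In all, 744 of 21239 differed, 392 higher and 352 lower in Spring. More were lower than higher with limma voom (1393 higher, 1668 lower), in a fit of only the 2 groups (667 and 888), with no filter (119 and 192), after thinning (153 and 161) and without Fall 6 (152 and 176), Fall 7 (162 and 170) or Fall 11 (108 and 123). The count became 267 without Fall 5, 328 without Fall 6, 332 without Fall 7, 419 without Fall 10, 231 without Fall 11, 353 without Spring 2, 267 without Spring 7, 247 without Spring 12 and 1179 without the library labelled Emergence spleen replicate 8. It was 2216 with DESeq2, 3061 with limma voom, 1555 in a fit of only the 2 groups, 311 with no filter and 314 after thinning.

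Identifiers that differed from Fall in Spring had mostly differed in Winter in the same direction. In skin, 1892 were higher at both times and 1473 lower at both, where independent lists would share 448 and 332, and 0 were opposite. In spleen, 280 and 268 were shared where 37 and 48 are given by independent lists, and 0 were opposite. Both comparisons use the same Fall libraries. Simulated data with no change gave 0 shared calls. Few calls were possible there, so this 0 does not show how many shared calls the common Fall libraries add. The correlations of the log2 changes were 0.44 in skin and 0.45 in spleen in these simulations, where the data gave 0.84 and 0.68. The covariances were 1.98 and 1.25 against 0.16 and 0.24 simulated. With the Fall libraries divided between the comparisons in 10 ways, the median shared count was 1538 in skin against 276 for independent lists, and 62 in spleen against 4, with median covariances of 1.84 and 1.06. These correlations are across identifiers, which are not independent replicates.

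Each library was placed on a scale from the Fall mean (0) to the Winter mean (1). In skin, Spring libraries lay closer to Fall on average than Emergence libraries did, though Spring replicate 1 (0.72) lay above Emergence replicate 6 (0.70). The median position over the 6438 skin identifiers called in Winter against Fall with an average log2 CPM of at least 1 was 0.86 ± 0.11 in Emergence and 0.57 ± 0.09 in Spring (n = 5 each, exact two-sided permutation p = 0.0159). Over 4525 spleen identifiers, chosen the same way without the library labelled Emergence spleen replicate 8, it was 0.74 ± 0.02 in 4 Emergence libraries and 0.42 ± 0.14 in 5 Spring libraries (exact two-sided permutation p = 0.0159). Spring replicates 1 and 9, rich in the 59 identifiers, lay at 0.57 and 0.55, and the other 3 Spring spleen libraries at 0.26 to 0.37. With the library labelled Emergence spleen replicate 8, which lay at 0.06, the Emergence mean was 0.60 ± 0.30 and the difference was not detectable (exact two-sided permutation p = 0.262). The smallest p these designs allow is 0.00794. Across all 4 times, 8454 skin and 3825 spleen identifiers changed. The spleen count was 5365 without the library labelled Emergence spleen replicate 8, 2297 without Fall 5, 2516 without Fall 10, 6674 with DESeq2, 8244 with limma voom and 1917 after thinning.

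**Figure D4:**
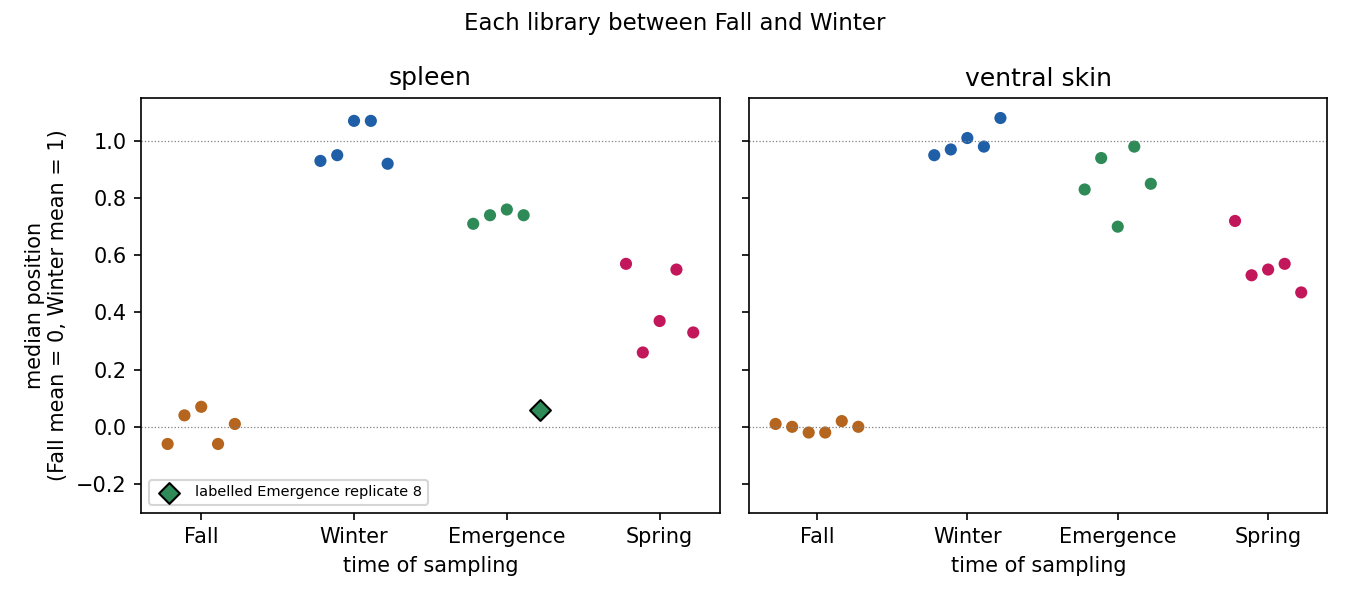
Median position of each library (vertical axis, no unit) between the Fall mean, set to 0, and the Winter mean, set to 1, by time of sampling, over 4525 spleen and 6438 skin identifiers called in Winter against Fall with an average log2 CPM of at least 1. Points are libraries and the diamond is the library labelled Emergence spleen replicate 8, at 0.06; the other Emergence spleen libraries lie at 0.71 to 0.76 and Spring spleen libraries at 0.26 to 0.57.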

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

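The tests of the frog of origin, of a difference of that frog and of the depth of the library labelled Emergence spleen replicate 8, of the tissue and time behind the 59 spleen identifiers, of library numbers, thinning and the splits of the spleen libraries were chosen only after the results they bear on were seen.

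The library labelled Emergence spleen replicate 8 stood far from its group, at 0.06 on the scale from Fall (0) to Winter (1), where the other 4 Emergence libraries lay at 0.71 to 0.76. Low depth is argued against, since the only shallower Emergence spleen library, with 3.2 M counts against 4.41 M, lay at 0.71. Over the frog-specific identifiers its own skin library ranked 6 of 21 (r 0.07), as an origin in another frog could give. A first selection of identifiers used the same cutoffs but kept the libraries of that label in the time means and filters. It gave rank 4 (r 0.12), short of the rank above 5 that the test asked for. The spleen library had an r of 0.90 with Fall ventral skin replicate 9, inside the 0.83 to 0.94 of the 17 other own-frog pairs. The spleen of that Fall frog is thus a candidate explanation. The deposited Fall spleen replicate 9 held 0 gene counts. A biological difference between the frog labelled Emergence 8 and the other Emergence frogs is argued against by the same r of 0.07, since such a frog would still match its own skin as the other 17 did. Its labelled skin library lay with the Emergence group, at 0.85, and Fall ventral skin replicate 9 with the Fall group, at -0.02. How the spleen library came by its label was not tested.

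The 59 identifiers that vary together took 27.4% of counts in Winter spleen replicate 7 against at most 1.11% in the rest of its group, 27.2% in Emergence spleen replicate 7 against at most 0.249%, and 1.69% in Fall spleen replicate 11 against at most 0.0586%, each far from its group. A single time of sampling as the cause is argued against, since the 4 richest libraries belong to 3 times. None of them is a Fall library, so a difference between Fall and the later times stays open. In the 7 other spleen libraries with more than 500 CPM in the 59 identifiers, the order of identifiers followed that of the 4 richest ones, with a lowest Spearman correlation of 0.69 across identifiers chosen without the library tested, which is consistent with 1 source in differing amounts, such as another tissue carried along in the dissection. In the 9 spleen libraries below that level, correlations over the 59 identifiers were -0.01 to 0.55, so the order is borne out only for the 7. Cells of the spleen itself whose share differs between frogs would give the same order and stay open, and no tissue is named here, since the identifiers have no gene names.

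Fall skin libraries stood apart from those of the other times: on the first principal component they lay at -127.9 to -110.6, and the lowest library of another time at -20.5. In spleen, Fall libraries lay at -135.9 to -47.0 and Winter libraries at 28.3 to 185.3, but Spring replicates 2, 7 and 12 and the library labelled Emergence spleen replicate 8 lay inside the Fall range. The 4 libraries rich in the 59 identifiers lay above all other spleen libraries of their times. They were Winter replicate 7 at 185.3, Emergence replicate 7 at 72.1 and Spring replicates 1 and 9 at 82.2 and 50.2. In spleen, time alone can therefore not be read from this component. The lower depth of Winter spleen as the whole cause of the spleen difference between Fall and Winter is argued against by the 29% called among spleen identifiers with an average log2 CPM above 5 (21.4% of the rest). It is also argued against by 2635 calls among 10828 tested after every spleen library was thinned to the smallest total. Library numbers largely ran with the time of sampling. The single Fall library numbered apart, Fall ventral skin replicate 9, lay at -125.3 on the first component, inside the range of the other Fall skin libraries. On the second component it lay at -117.5, outside their range: Fall skin replicate 10 lay at -89.6 and the rest at 41.0 to 48.5. With 1 such library, the order of preparation and the season cannot be told apart. Reads outside the gene models also set Fall skin apart, at 3.20 to 3.76% of tallied reads against 4.21 to 5.61% at the other times. The source of that difference was not tested. A seasonal difference remains a hypothesis, which no other year or place here can test.

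Among 85 groups of 4 to 10 libraries and values examined, 19 had 1 library far from the others, where the rule takes chance to give about 1 in 20. That rate need not hold here, since shares and CPM are skewed and part of the values are of identifiers chosen for large changes. The 19 are therefore not read as an excess over chance. Besides those above, Winter spleen replicate 3 held 12.2 M counts against at most 2.97 M in the rest of its group. Emergence spleen replicate 1 had 53.8% of reads with several alignments against at most 12.2%, and 11.6% of reads outside the gene models against at most 4.84%. Spring spleen replicate 12 had 4.71% of reads outside the gene models against 5.19 to 5.26%. Spring ventral skin replicate 1 lay at 54.5 on the first principal component against -20.5 to -2.90 in the rest of its group.

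Among named identifiers, single libraries also stood far from their group. MSTRG.2383 was at 31.1 CPM in Fall spleen replicate 6 against at most 4.19, and MSTRG.541 was at 398 CPM in Fall spleen replicate 11 against at most 247. MSTRG.28888 was at 28.4 CPM in Emergence spleen replicate 5 against at most 5.84. In Spring spleen, MSTRG.37442 was at 0.0667 CPM in replicate 7 with no counts in the others, and MSTRG.541 was at 7.64 CPM in replicate 1 against at most 2.49. In skin, MSTRG.15881 was at 3410 CPM in Spring replicate 1 against at most 548, and at 0.453 CPM in Fall replicate 7 against at most 0.166. MSTRG.46208 was at 21.7 CPM in Emergence ventral skin replicate 6 against at most 12.4, MSTRG.6696 at 12.9 CPM in Emergence ventral skin replicate 8 against at most 2.72, and MSTRG.4062 at 115 CPM in Fall ventral skin replicate 9 against at most 24.7.

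The change from Fall to Winter differed between tissues, by a direct test, for 709 identifiers. The skin minus spleen difference in fitted log2 change was 3.77 for MSTRG.21991, 8.98 for MSTRG.14461, -15.27 for MSTRG.40325 and -7.61 for MSTRG.40327. The last of these rested on Winter spleen replicate 3, without which its difference was -1.89 (adjusted p 1, edgeR). The value for MSTRG.40325 is a fitted one with 2 counts in Winter skin, and is no bound. It was -16.13 without Fall spleen replicate 11, -15.88 without Winter skin replicate 3 and -14.33 without Winter spleen replicate 3 (adjusted p 0.0456 in the last case, edgeR). The count of 709 fell to 257 without Fall spleen replicate 10, and the report gives the other libraries that move it. Among libraries not used, Emergence ventral skin replicate 1 held 5 counts, above the 3 that a count of 0 allows.

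Other splits of the same libraries into groups of the same sizes were tested for each count. For Winter against Fall, 1 of 100 splits, the real one, gave as many calls: in spleen the real count was 4888 and the highest other 6, in skin 8967 and 5143, and for differences between tissues, where frogs were split, 709 and 263. For Spring against Fall, 1 of 100 gave as many, with 744 and a highest other of 61 in spleen and 3963 and 1338 in skin. Across the 4 times, 1 of 100 gave as many, with 3825 and 622 in spleen and 8454 and 565 in skin. The share is under 0.05 for each of these counts, which argues against chance without excluding it. For differences between tissues, the count of 257 without Fall spleen replicate 10 lies below the highest other of 263.

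For Spring against Emergence, 4 of 100 splits gave as many as the 32 calls in spleen, with a highest other of 903, and 2 of 100 as many as the 219 in skin, with a highest other of 1154. Both shares are under 0.05 and the median of the other splits was 0 in both, but single splits with several times the real count point to a structure of the libraries, whose source was not tested. The spleen count itself is 0 without Emergence replicate 5, Spring 2 or Spring 7 and 687 without the library labelled Emergence spleen replicate 8. The skin count is 23 without Spring replicate 7 and 558 without Spring replicate 1. For Emergence against Winter the real counts were 0 in edgeR. Every split reaches 0, so 100 of 100 gave as many by necessity and the splits could not bear on chance. The highest others were 12 in spleen, 678 in skin (median 0), which again points to such a structure, and 5 for differences between tissues. The real groupings had 2648, 2157 and 1903 identifiers at an unadjusted p under 0.05 (edgeR), and DESeq2 called 252, 137 and 114. For differences between tissues in Spring against Emergence, the count was also 0 in edgeR (2387 at an unadjusted p under 0.05, DESeq2 265). There 35 of 35 splits gave as many, again by necessity, with a highest other of 2.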

How the results depend on the processing

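Thinning, the fits without the library labelled Emergence spleen replicate 8 or without the 4 libraries rich in the 59 identifiers, and the contrasts Emergence against Fall and Spring against Winter were chosen only after the data were seen. Winter against Fall and the joint test across times in skin, and skin Spring against Fall and Emergence against Fall, stayed within 1.5 times their counts under the alternatives run, except the title-number block. Other counts moved as follows, and where fewer libraries or identifiers in the fit do not show it, the cause was not tested. Low depth limits Winter spleen most. The minimum of 10000 counts keeps the same 41 libraries, and the 5 M minimum removes no skin library and, besides Emergence spleen 1 and 8 and Spring spleen 9, leaves out all but 1 Winter spleen library, assumed to vary like the other groups, so skin values do not change under either. The gene list alternatives were not run, since no list matched.

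With the 5 M minimum, spleen counts were 495 for Winter against Fall (4888), 1 for Emergence against Winter (0), 348 for Spring against Emergence (32), 2895 for Emergence against Fall (1266) and 1 for Spring against Winter (1074), and differences between tissues 97 (709) for Winter against Fall and 8 (0) for Emergence against Winter. After thinning, 10828 spleen identifiers were tested in place of 21239. Spleen counts were then, in the same order and with Spring against Fall (744), 2635, 1, 14, 513, 431 and 314, with 1917 across times (3825) and 170 differences between tissues for Winter against Fall. With no filter, spleen counts were 0 for Spring against Emergence, 311 for Spring against Fall, 596 for Emergence against Fall and 405 for Spring against Winter, skin counts 69 for Spring against Emergence (219) and 485 for Spring against Winter (1171), and differences between tissues 323 for Winter against Fall.

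DESeq2 gave in spleen 252 for Emergence against Winter, 1090 for Spring against Emergence, 2216 for Spring against Fall, 2902 for Emergence against Fall, 2441 for Spring against Winter and 6674 across times. In skin it gave 137 for Emergence against Winter, 1074 for Spring against Emergence and 2350 for Spring against Winter, and differences between tissues of 1678, 114 and 265 for Winter against Fall, Emergence against Winter and Spring against Emergence. Limma voom gave in spleen 1403 for Spring against Emergence, 3061 for Spring against Fall, 4066 for Emergence against Fall, 3455 for Spring against Winter and 8244 across times, in skin 1 for Emergence against Winter and 141 for Spring against Emergence, and between tissues 1669 for Winter against Fall and 8 for Spring against Emergence.

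The fit of only the 2 groups gave in spleen 0 for Spring against Emergence, 1555 for Spring against Fall, 140 for Emergence against Fall and 529 for Spring against Winter, and in skin 1 for Emergence against Winter, 11 for Spring against Emergence and 463 for Spring against Winter. The naming covariate gave 4 for spleen Spring against Emergence and 1 for skin Emergence against Winter. Without the 4 libraries rich in the 59 identifiers, spleen counts were 344 for Spring against Emergence, 701 for Emergence against Fall and 1850 for Spring against Winter. DESeq2 size factors gave 489 differences between tissues for Winter against Fall, with 40.7% more positive in skin in place of 66.6%, and the share was also under 50% in 7 of 21 fits that left out 1 Fall or Winter library.

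With the frog as a replicate block, differences between tissues were 263 for Winter against Fall and 1 for Emergence against Winter, and 408 and 2 without the library labelled Emergence spleen replicate 8. Title numbers do not pair libraries across times: deviations from group means of same-numbered libraries had a median r of 0.04 over 13 pairs in spleen (-0.28 to 0.28) and -0.06 over 16 in skin (-0.21 to 0.25). With that number as a replicate block, spleen counts were 687 for Winter against Fall, 3 for Spring against Emergence, 0 for Spring against Fall, 44 for Emergence against Fall, 0 for Spring against Winter and 192 across times. Skin counts were 5780, 1, 495, 4035 and 6 in the same order and 3818 across times.

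With 1 library left out, spleen counts ranged from 3354 to 5443 for Winter against Fall, 0 to 13 for Emergence against Winter, 0 to 687 for Spring against Emergence, 231 to 1179 for Spring against Fall, 369 to 3515 for Emergence against Fall, 167 to 1655 for Spring against Winter and 2297 to 5365 across times. Skin counts ranged, in the same order, from 7882 to 8628, 0 to 2, 23 to 558, 3093 to 3407, 6726 to 7956, 475 to 1763 and 7448 to 9117. Differences between tissues ranged from 257 to 748, 0 to 1 and 0 to 33 for the 3 contrasts. Of the calls of named identifiers, 297 were kept and 55 lost with 1 library left out, 192 were kept and 45 lost under other settings, 14 of them with the title-number block, and none was reversed. Under the other settings, cases where the identifier did not pass the count filter or had no p-value are in neither number.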

Other observations

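The sets of identifiers enriched in 1 tissue and the contrasts Emergence against Fall and Spring against Winter were chosen only after the data were seen.

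Identifiers enriched in the spleen took a smaller share of ventral skin counts at each time after Fall than in Fall. Of 1382 identifiers at least 16-fold higher in spleen than in skin, 382 were tested in skin, and 244 of them fell and 5 rose between Fall and Winter, with a median log2 change of -1.94, while over all 22806 tested in skin 4425 fell and 4542 rose. The set took 1.08 ± 0.506% of skin counts in Fall (n = 6), 0.11 ± 0.0416% in Winter, 0.15 ± 0.0385% in Emergence and 0.106 ± 0.0213% in Spring (n = 5 each). Between Fall and Spring, 115 fell and 2 rose. In the spleen itself, 277 of 1247 tested members fell and 50 rose between Fall and Winter. Identifiers at least 16-fold higher in skin (2449) took 37.6 ± 1.55% of skin counts in Fall, 28.9 ± 3.38% in Winter, 25.7 ± 1.9% in Emergence and 29.4 ± 2.05% in Spring; 581 of 2447 tested members rose and 397 fell in skin between Fall and Winter. The sets were defined on these same libraries. The 382 had a median average log2 CPM of 0.05 in skin, against 2.4 for identifiers enriched in neither tissue. At such levels, members could pass the count filter through Fall alone, where the set was highest. The excess of falls among the tested members may thus be set in part by the filter. The shares of counts take all 1382 members and do not depend on that filter.

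In ventral skin, 7701 identifiers differed between Emergence and Fall, 4211 higher and 3490 lower in Emergence, and 1171 between Spring and Winter, 667 higher and 504 lower in Spring (772 and 822 with limma voom). The count of 1171 became 766 without Winter replicate 7, 491 without Winter 9, 737 without Winter 5, 1763 without Spring 1, 598 without Spring 7, 600 without Spring 8, 494 without Spring 9 and 475 without Spring 12. Among 100 splits of the libraries, 1, the real one, gave as many calls for each, with highest others of 4051 and 436. Both shares are under 0.05, which argues against chance without excluding it.

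In the spleen, 1266 identifiers differed between Emergence and Fall, 903 higher and 363 lower in Emergence. The excess of higher ones was smaller without the library labelled Emergence spleen replicate 8 (1934 higher and 1581 lower of 3515) and with the 5 M minimum, which also leaves out that library and Emergence replicate 1 (1569 and 1326), and turned with limma voom (1901 and 2165). The count of 1266 became 369 without Fall replicate 5, 523 without Fall 6, 453 without Fall 10, 480 without Fall 11, 624 without Emergence 1, 696 without Emergence 2, 674 without Emergence 5 and 702 without Emergence 7. Between Spring and Winter, 1074 differed, 824 higher and 250 lower in Spring. This became 461 without Winter 3, 399 without Winter 6, 555 without Winter 7, 536 without Winter 9, 167 without Spring 2, 320 without Spring 7, 235 without Spring 12 and 1655 without the library labelled Emergence spleen replicate 8. For Emergence against Fall, 1 of 100 splits gave as many calls (highest other 1203), and for Spring against Winter 3 of 100 (highest other 2187); both shares are under 0.05.

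Identifiers with adjacent numbers were called in the same direction in ventral skin between Fall and Winter more often than after shuffling. Of 12141 adjacent pairs, 1585 had both members called in the same direction, against a mean of 938 and a highest of 1048 in 10000 shuffles (one-sided permutation p = 0.0001, the smallest these shuffles can give). Within times, the median r of adjacent pairs over the 21 skin libraries was 0.18, against 0.01 for shuffled pairs. An r above 0.8 was found for 6% of adjacent pairs, against 0.0329% of shuffled pairs. A hypothesis consistent with this is that these are fragments of 1 gene model or neighbouring genes counted under adjacent numbers, in which case the number of genes that changed may be lower than the number of identifiers. The files do not tell fragments from neighbours. Among the identifiers named for spleen, MSTRG.541 and MSTRG.542 have adjacent numbers. Their means were 256 and 16.1 CPM in Fall spleen, and 0.538 and 0 in Winter spleen. Whether they are parts of 1 gene was not tested.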
